A study of Brachypodium distachyon with 2 samples.

How the data were processed

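Small RNA from panicles of Brachypodium distachyon Bd21 was measured in 1 library, panicles_UD. The labels list a second library, panicles_OSU, which was not analysed here. Per the labels' protocols, small RNA was size-fractionated from total RNA, adapters were ligated to both ends, the products were amplified by RT-PCR, and sequencing was on an Illumina Genome Analyzer. The base caller and any quality filter are not given in the sources used here. The table used lists each distinct 36-nt read with its abundance. Per the file headers the reads are untrimmed and the abundance is the count of times a read was seen, a raw count that was not normalized. The series' design text describes removal of the 3' adapter, but the reads in this table still held it. The values were whole numbers of at least 1, and no read was listed more than once or held a base other than A, C, G or T. The count of a sequence is a number of amplified reads without molecular identifiers, so it also reflects amplification and ligation efficiency.

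Among 5 adapter sequences listed before the data were examined, the first 8 nt of the Illumina small RNA 3' adapter, TCGTATGC, occurred in the most reads, 4818639 of 5390259 (89.4%). Each read was trimmed at the first exact match of these 8 nt, and reads without it were left out. Inserts of 18 to 30 nt were kept and identical inserts were summed. An insert could not exceed 28 nt, because the 8 nt had to fit in the 36-nt read. Shares were taken over all kept inserts, and levels are reads per 1000000 kept inserts (RPM), so fragments of ribosomal RNA and of the 5' adapter are part of the denominator. The 4677547 kept reads give a limit of detection of 3 reads, or 0.641 RPM.

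An insert of 19 to 24 nt was assigned to a family when it aligned without gaps to 1 of 63 listed sequences, with each end shifted by at most 2 nt and with at most 2 substitutions. The best match decided, and ties went to the family listed first. The sequences and their 7 functional groups were written from general knowledge of conserved plant miRNAs and TAS3 siRNAs before the data were examined. They are not a set annotated in Brachypodium, so a family with a diverged sequence would be missed. The list held 32 miRNA families, TAS3, and 9 dicot-only or animal families that served as background with shuffled sequences. The RefSeq gene table of the Brachypodium_distachyon v3.0 assembly was used only for the number of miRNA genes per family. It held 310 miRNA genes in 183 families, and 30 of the listed families had at least 1 gene. No coordinate is given, because no build is named for the reads.

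The named families were fixed before the data were examined: the 20 most abundant by group, the phased siRNA triggers and TAS3 at any level, and the 10 most abundant sequences outside the list. Families with fewer reads that are named as undetected or low fall outside that rule and were chosen after their values were seen. The 5' adapter, 5.8S ribosomal RNA, tRNA-Ala and tRNA-Gly references were listed after the most abundant sequences had been seen, again from general knowledge, and an insert was counted as a fragment when it shared 16 nt exactly with one of them.

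Paired small RNAs were counted as distinct sequences of 1 length whose reverse complements overlap at the 5' ends. For a duplex with 3' overhangs of 2 nt, the overlap is 19 nt for 21-nt sequences and 22 nt for 24-nt sequences. The number of sequences with such a partner was divided by the mean number at the 4 overlaps 1 and 2 nt shorter or longer. This count was chosen after seeing the data. It includes both strands of a pair, so intervals that treat sequences as independent are too narrow for it.

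No test between groups was made. Shares have exact (Clopper-Pearson) binomial intervals and read numbers exact Poisson intervals at a level of 95%. The alternatives to the trimming, the insert range, the depth, the substitutions and the minimum number of reads were listed before the data were examined. Without a genome sequence, 4 planned results were not run: the genome-matched share, 21-nt phased loci, 24-nt phased loci and 24-nt reads upstream of genes. The alternative of using genome-matched reads only was not run for the same reason.

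The steps were tested on simulated data. Of 100000 random inserts, with read errors at an assumed rate, the adapter was found in 96.1%, and 99.98% of those had the right length. In the library itself it was found in 89.4% of the reads. Listed sequences planted with 0, 1 or 2 substitutions, without read errors or shifted ends, were assigned to their family in 100% of cases. With 3 substitutions 0.66% were. The 100% follows from the substitution limit, so it checks the code only. No random insert was assigned to a family, and 4000 of 4000 planted duplex strands were found. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.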

Results

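Small RNA was sequenced from panicles of wild-type Brachypodium distachyon, a small temperate grass used as a model for cereals, in the inbred line Bd21. The labels give 2 panicle libraries that differ in where and how the plants were grown. The library analysed here, panicles_UD, came from plants kept for 42 days at 20 °C with 20 h of light and 4 h of dark. The other, panicles_OSU, came from plants kept for 28 to 35 days at 25 °C with 16 h of light and 8 h of dark, and was not analysed here. With 1 library there were no replicates and no comparison between growth conditions, so no p-value is given. Intervals are 95% intervals for counting error only, exact binomial for shares and exact Poisson for reads of a family or sequence. Amplified reads without molecular identifiers are not independent molecules, so the intervals do not cover the variation between plants or library preparations.

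The panicles_UD library held 5390259 reads of 36 nt, which were 2608482 distinct reads. The 3' adapter was found in 4818639 reads (89.4%). After it was removed, 4677547 reads had an insert of 18 to 30 nt, the longest being 28 nt, and these were 1942545 distinct sequences. One read was worth 0.214 reads per 1000000 inserts (RPM), and 3 reads, taken as the limit of detection, 0.641 RPM. Of the distinct inserts, 82.9% were read once.

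The first question was which size classes the panicle library contained. Length alone does not show which pathway made a small RNA. The 24-nt class, the usual size of the small interfering RNAs (siRNAs) that direct DNA methylation at plant repeats, was the most abundant, with 2204791 reads or 47.1% of inserts (47.1 to 47.2). The 21-nt class, the usual size of plant microRNAs (miRNAs) and trans-acting siRNAs, held 965718 reads or 20.6% (20.6 to 20.7). The 24-nt class therefore had 2.28 times the reads of the 21-nt class. This ratio was 4.50 without the family miR168, which held 49.3% of the 21-nt reads, and 1.42 without sequences read once. The 23-nt class took 10.96% of the reads, the 22-nt class 5.07% and the 20-nt class 4.19%. Lengths of 21 to 24 nt together made up 83.8%.

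The size classes differed more in sequence diversity than in reads. There were 1233580 distinct 24-nt sequences, 63.5% of all distinct inserts (63.4 to 63.6), against 143757 of 21 nt, 7.40% (7.36 to 7.44), a ratio of 8.58. A distinct 24-nt sequence had on average 1.79 reads and a distinct 21-nt sequence 6.72. At random thinning of the reads to 50%, 55.8% of the distinct sequences were still seen, so the number of distinct sequences had not levelled off at this depth.

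The 5' base, which in plants helps to sort small RNAs among Argonaute proteins, also differed between the classes. Of the 24-nt reads 42.7% began with A (42.6 to 42.7), and of the distinct 24-nt sequences 43.3%. Of the 21-nt reads 66.1% began with U (66.01 to 66.19), but of the distinct 21-nt sequences only 34.3% did. A single family, miR168, carried most of this U: without it, 33.3% of the 21-nt reads began with U and 25.5% with C. The 22-nt reads showed no such leading base, with 28.2% U and 27.1% A.

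**Figure D1:**
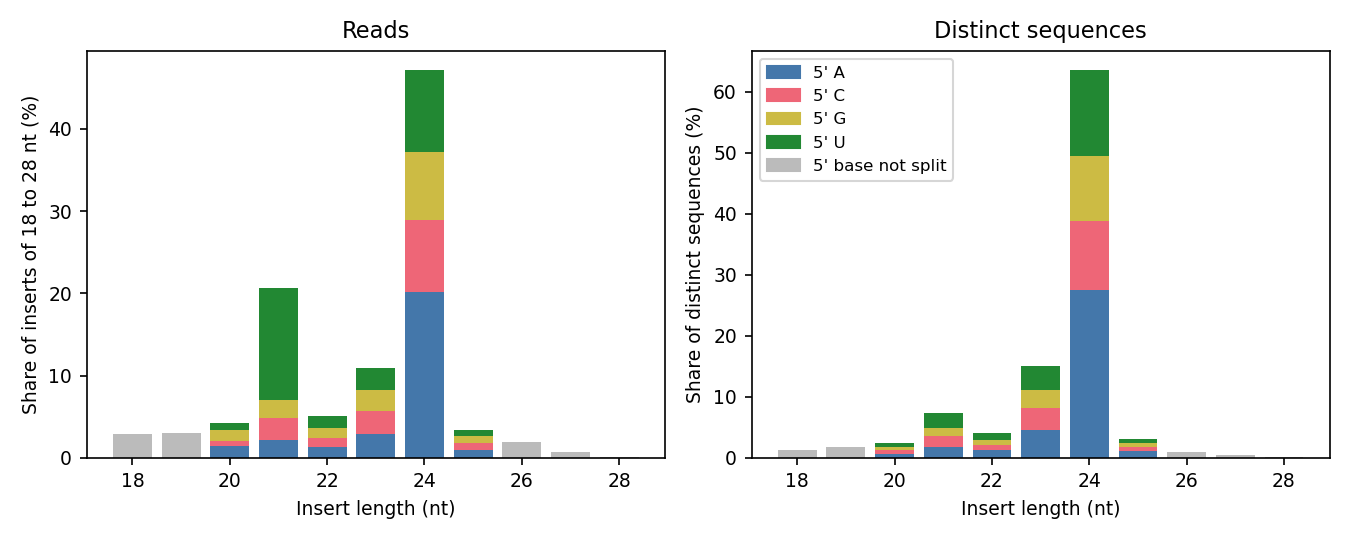
Share of inserts by length (nt) in the panicles_UD library, as a percentage of reads (left) and of distinct sequences (right), with the bars of 20 to 25 nt divided by 5' base. The 24-nt class leads in both, at 47.1% of reads and 63.5% of distinct sequences, while the 21-nt class falls from 20.6% to 7.40%.

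The second question was which conserved miRNA families were present in the panicle. Families on a list fixed before the data were examined took 559064 reads, 11.95% of the inserts, in 22 of 32 families at 10 reads or more. A further 4 families had 1 to 9 reads. No read was assigned to miR162, miR398, miR408, miR2118, miR437 or miR530, for which the exact Poisson upper bound was 0.789 RPM each. This bound covers counting error only and holds for the listed sequences, which are not a set annotated in Brachypodium. A wider search, within 4 substitutions, was made only for miR2118 and miR2275, so diverged forms of the others would be missed. The background of the matching was low: 10 sets of shuffled family sequences took between 0 and 1 reads each, 5 dicot-only families took 0 reads and 4 animal families took 1. This background covers matches of unrelated sequences, not reads that a listed family took from a related one. The only read of miR535, with 2 substitutions, was a 21-nt form of miR156 without 1 base.

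The family of the silencing machinery group, miR168, which targets the mRNA of ARGONAUTE1, exceeded all others. It held 480075 reads or 102634 RPM (102344 to 102925), which was 85.9% of the miRNA reads and 10.3% of all inserts. Its 21-nt forms, with 475995 reads, were 49.3% of the 21-nt reads. The miR168 reads of all lengths were 14.1 times those of the next family, miR166. The RefSeq annotation of the Brachypodium_distachyon v3.0 assembly lists 1 gene of the miR168 family and 9 of miR166. The other member of this group, miR162, which targets DICER-LIKE1 mRNA, had 0 reads that matched the listed sequences. The listed miRNA families other than miR168 together had 78989 reads, 1.69% of the inserts.

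All 8 families of the developmental transcription factors group reached 10 reads, with 8842 RPM in total. The most abundant was miR166, a regulator of class III homeodomain-leucine zipper genes, at 7261 RPM (7184 to 7339). Its sequence TCGGACCAGGCTTCATTCCCC had 17688 of the 33965 family reads. It was followed by miR164, which targets NAC genes, at 485.5 RPM, miR169, which targets nuclear factor Y subunits, at 392.1 RPM with 18.05% of its reads free of substitutions, miR396, which targets growth-regulating factors, at 274.7 RPM, and miR159, which targets MYB genes, at 215.7 RPM. Lower levels were found for miR171 (115.7 RPM), miR319 (52.6 RPM) and the monocot family miR444 (44.7 RPM), which targets MADS-box genes. Of the miR444 reads, 105 of 209 matched a listed sequence without a substitution.

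The phase change and flowering group held 5920 RPM, with 4 of 5 families at 10 reads or more. Of these miR172, which represses APETALA2-like genes, had 3653 RPM (3599 to 3709), above miR156, which represses SQUAMOSA promoter binding protein-like genes and is typical of the juvenile phase, at 2197 RPM (2154 to 2240). The miR156 reads were divided between a 20-nt form, TGACAGAAGAGAGTGAGCAC, with 5154 reads and a form 1 nt longer at the 5' end, TTGACAGAAGAGAGTGAGCAC, with 4193. The related family miR529 had 46.8 RPM. The grass family miR5200, which targets FLOWERING LOCUS T-like genes in Pooideae, had 105 reads or 22.4 RPM (18.4 to 27.2). None of these matched the listed sequence without a substitution, and the main form, TGTAGATACTCCCTAAGGCTT, had 93 reads.

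All 5 families of the auxin signalling group, the trans-acting siRNAs of TAS3 included, reached 10 reads, with 2372 RPM in total. Most came from miR167, a regulator of AUXIN RESPONSE FACTOR genes, at 1963 RPM (1923 to 2003). Its 22-nt form TGAAGCTGCCAGCATGATCTGA had 4480 reads and its 21-nt form TGAAGCTGCCAGCATGATCTA 2962. The TAS3 siRNAs, which also target AUXIN RESPONSE FACTOR mRNAs, had 330.5 RPM, and miR390, the miRNA that starts their production, 17.5 RPM. Of the TAS3 reads 9.12% (141 of 1546) matched a listed sequence without a substitution, against 75 of 82 for miR390, so the TAS3 level rests on matches with substitutions. Their most abundant sequence was TCTTGACCTTGTAAGACCCAA with 1149 of 1546 reads. The receptor-targeting miR393 had 35.3 RPM and miR160 had 26.1 RPM, with 79 of its 122 reads free of substitutions.

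The nutrient and copper group was low, at 61.6 RPM, and 3 of its 7 families reached 10 reads. Most of it was the monocot family miR528 at 52.4 RPM. The sulphate-responsive family miR395, with 16 annotated genes the largest set among the families named here, had 20 reads or 4.28 RPM. The remaining group of 4 families held 21.8 RPM, mainly miR1432 at 14.97 RPM, of which 27.1% of the reads matched without a substitution. No read matched the listed sequences of miR398 or miR408, which target copper protein mRNAs.

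The families known to trigger the phased siRNAs of grass inflorescences were at or under the limit of detection. No read was assigned to miR2118, the trigger of 21-nt phased siRNAs, and 1 read to miR2275, the trigger of 24-nt phased siRNAs. The upper bound was 0.789 RPM for miR2118 and 1.19 RPM for miR2275, which was measured at 0.214 RPM. The same annotation lists 1 gene of miR2118 and 3 of miR2275. Phased loci themselves were not analysed here, because no genome sequence was used.

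**Figure D2:**
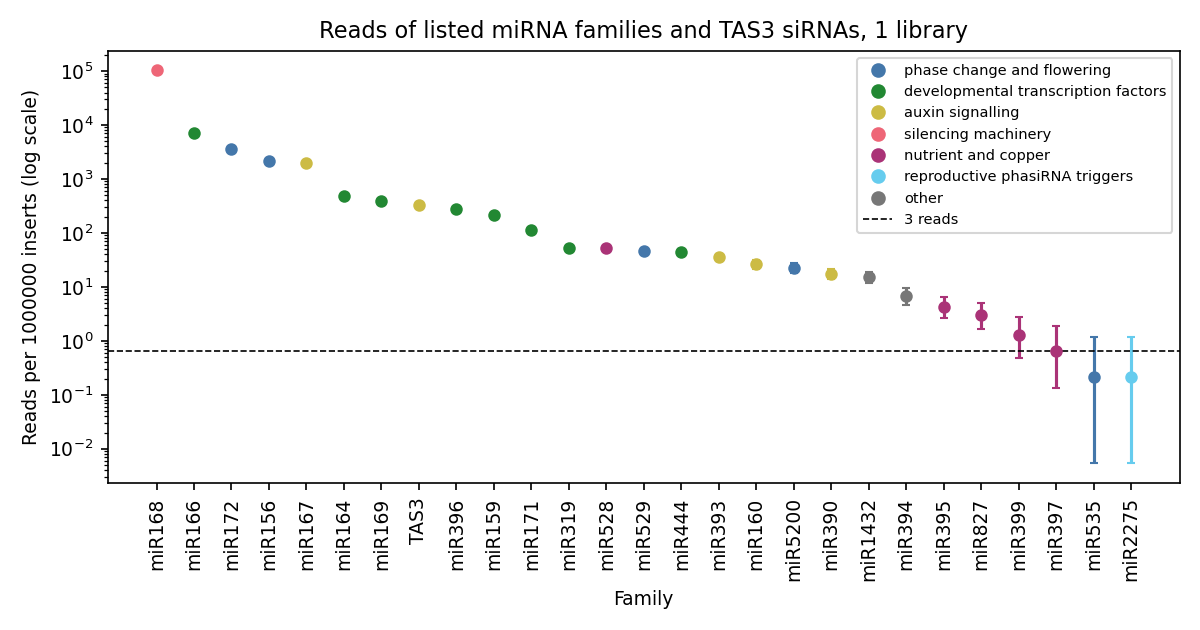
Reads per 1000000 inserts (log scale) of each listed miRNA family and of the TAS3 siRNAs with at least 1 read in the panicles_UD library, with exact Poisson 95% intervals, coloured by group. The dashed line is the limit of detection of 3 reads (0.641 RPM). The family miR168 stands at 102634 RPM and the next, miR166, at 7261 RPM.

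Outside the listed families, the 10 most abundant sequences were all fragments of the 5' adapter or of 5.8S ribosomal RNA. The first was TTCTACAGTCCGACGATC, the 3' end of the 5' adapter, with 38583 reads or 8249 RPM. The second, CACGACTCTCGGCAACGGATATCT, had 29863 reads or 6384 RPM and lies near the 5' end of 5.8S ribosomal RNA. In all, fragments of 5.8S ribosomal RNA made up 5.46% of the inserts and fragments of the 5' adapter 3.11%. Inserts that matched the listed 5' part of a tRNA-Ala made up 1.06%, and that of a tRNA-Gly 0.0168%. These 4 references together took 451252 reads or 9.65%. Other forms of tRNA-Ala and tRNA-Gly were not searched, so these values are not totals for either. Other ribosomal and transfer RNAs were not searched, so structural RNA may take a larger share. The 5.8S fragments were most numerous at 24 nt, with 24.7% of them, where they were 2.86% of the reads, and they were 37.6% of the less frequent 26-nt reads. The 5' adapter fragments were 32.3% of the 18-nt reads.

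Small RNAs cut from paired RNA occur as duplexes with 2-nt 3' overhangs, and both strands of such duplexes were found, in a count chosen after seeing the data. Of the 143757 distinct 21-nt sequences, 4330 or 3.01% (2.92 to 3.10) had an exact partner at the overlap of 19 nt that such a duplex has. At an overlap of 18 nt 0.728% had a partner, and at 20 nt 0.650%. Among the distinct 24-nt sequences, 34275 or 2.78% (2.75 to 2.81) had a partner at the corresponding overlap of 22 nt, where 21 nt gave 2.36% and 23 nt 2.12%. Shorter overlaps of 24-nt sequences were as frequent or more so, with 2.80% at 19 nt and 2.99% at 18 nt. Relative to the mean of the 4 neighbouring overlaps, the frequency was 5.17 times (4.94 to 5.41) for 21 nt and 1.22 times (1.20 to 1.23) for 24 nt. It was 2.02 times (1.56 to 2.60) for 20 nt, from 96 sequences, 1.24 times (1.05 to 1.46) for 22 nt, 0.987 times (0.944 to 1.03) for 23 nt and 1.17 times (0.917 to 1.49) for 25 nt. Both strands of a pair were counted, while the intervals treat sequences as independent, so all intervals for pairs are too narrow. With its lower end at 1.05, a ratio above 1 is not shown for 22 nt. Among sequences with at least 2 reads, the ratio was 15.1 for 21 nt, 1.68 for 24 nt and 1.14 for 23 nt. For the other lengths it rested on few sequences, with 0.5 for 22 nt from 4, 0.8 for 25 nt from 3 and 2 for 20 nt from 2.

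**Figure D3:**
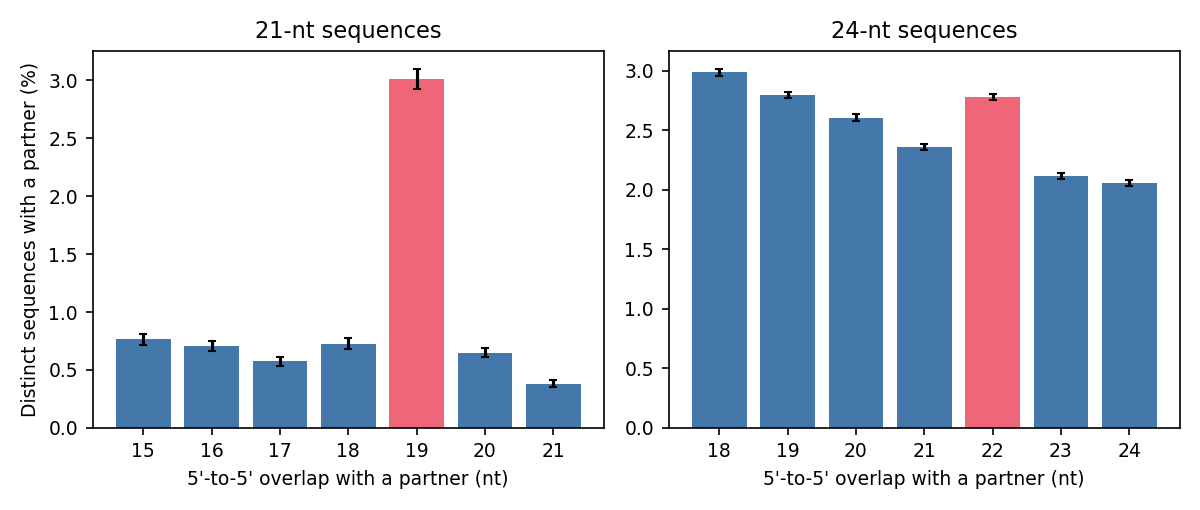
Percentage of distinct 21-nt (left) and 24-nt (right) sequences with a reverse-complementary partner of the same length, by the overlap of their 5' ends (nt), with exact binomial 95% intervals. The intervals are too narrow, because both strands of a pair were counted. The red bar marks the overlap of a duplex with 2-nt 3' overhangs, with 3.01% at 19 nt on the left and 2.78% at 22 nt on the right, where 19 nt and 18 nt are at 2.80% and 2.99%.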

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

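The look-alike test of miR168, the miR167 length test, the thinning of 21-nt inserts and the range over other ends were chosen after the results were seen, and the other tests in this part before. The library held 4 sets of reads that gave no value for a listed family in the main trimming, each above the limit that a count of 0 allows. They were 571620 reads without an exact match of the adapter, 141092 reads with an insert under 18 nt, 145275 inserts that hold part of the 5' adapter, and 1748 reads of 36 nt made of C alone. The reads of C alone are also among those without an exact match. Of the reads without an exact match, 390382 held the adapter start with 1 mismatch, which left 181238 reads, 3.36% of the library, with neither.

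The first pattern was the level of miR168, at 14.1 times the next family from 1 annotated gene. Look-alike sequences taken in by the substitution limit are argued against, because 93.5% of its reads matched the listed sequence without a substitution. A preference of ligation or amplification for the bases at the insert's ends stays open. Other 21-nt inserts with the same last 4 bases, GGAC, had 0.773 times (0.632 to 0.931, bootstrap) the reads per distinct sequence of the rest, and those with the same first 4, TCGC, 0.528 times (0.410 to 0.680), both under the bound of 10 set beforehand. That bound was too high to decide: thinning the inserts to 10% of their reads lowered the measure 1.47 times, while the 5th to 95th percentiles over other 4-base ends with at least 100 sequences already spanned 0.460 to 1.81 (last bases) and 0.471 to 1.67 (first bases). The medians over these other ends were 0.684 (last bases) and 0.693 (first bases), so a ratio under 1 was usual. A preference for the whole sequence or its fold was not tested, nor was any biological explanation, because the library has no second group beside it.

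The second pattern was the near absence of miR2118 and miR2275. Brachypodium sequences that differ from the listed ones are argued against as far as 4 substitutions: 3 reads lay within 4 substitutions of either family, with an upper 95% bound of 8.77, and 20 sets of shuffled sequences had 0 to 3. The requirement on that upper bound was added after the value was seen. A near-total loss of 22-nt inserts is argued against by miR167, whose 22-nt form had 1.51 times the reads of its 21-nt form. These forms end in different bases and their true ratio is unknown, so a partial loss cannot be measured from them. More diverged sequences, a preference of ligation or amplification against these families, and the stage of the panicles when they were collected were not tested and stay open.

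Of the 24-nt sequences read once, 3.58% (35845 of 1001754) lay 1 substitution from a 24-nt sequence with at least 10 reads. Errors of 1 substitution in such abundant 24-nt sequences therefore account for few of them. Errors in sequences with fewer reads or of other lengths, and reads with more changes, were not counted, so the share of errors as a whole is unknown.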

How the results depend on the processing

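Of 46 alternatives to the values, 38 moved a value beyond its 95% interval (for a count of families, by over 1.5 times) and 8 did not. At this depth these intervals are narrow. Most of the 8 were counts of families, and 22 of 32 families could not rise by over 1.5 times. None turned a direction, but a single share or count has no direction to turn, so for these that outcome was fixed in advance. Every alternative that gives both shares left the 24-nt share of reads above the 21-nt share. Seeds with 1 mismatch, omission of fragments of the 4 adapter and structural RNA references, omission of miR168, and both duplex alternatives were chosen after seeing the data. The causes of the shifts were not tested, except where the alternative itself sets them.

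With an adapter seed of 6 nt, the 21-nt share of reads was 20.9%, the 24-nt share 46.6%, the 24-nt share of distinct sequences 63.0%, the 5' U share of 21-nt reads 65.3% and the miRNA share 11.9%. With a seed of 12 nt, which limits inserts to 24 nt, these were 22.4%, 49.3%, 66.3%, 66.7% and 13.1%, and the 5' A share of 24-nt reads was 43.0%. Over inserts of 20 to 25 nt, the 21-nt share was 22.6%, the 24-nt share 51.6%, the 24-nt share of distinct sequences 66.5% and the miRNA share 13.0%. Without sequences read once, the 21-nt share was 27.6%, the 24-nt share 39.2%, the 24-nt share of distinct sequences 69.9%, 5' U 70.6% and 5' A 42.8%. Thinning to 50% gave 64.0% of distinct sequences at 24 nt. The miRNA share was 10.97% with no substitution and 11.8% with at most 1.

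Without fragments of the 4 adapter and structural RNA references, the 21-nt share was 21.8%, the 24-nt share 50.4%, 5' U 69.0%, 5' A 43.9% and the miRNA share 13.2%. Fragments of other structural RNAs were not removed. Without miR168, the 21-nt share was 11.7%, the 24-nt share 52.5% and 5' U 33.3%, so 1 family decides the 21-nt values. With a seed of 8 nt and 1 mismatch, the 21-nt share was 20.4%, the 24-nt share 47.4% and the miRNA share 11.5%. Families with at least 10 reads numbered 21 to 22 over the exact seeds, the substitution limits and the thinning, 26 at a minimum of 1 read and 17 at 100 reads. The 21-nt duplex ratio of 5.17 was 15.1 without sequences read once and 5.85 against longer overlaps only, and the 24-nt ratio of 1.22 was 1.68 and 1.33.

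Not run without a genome sequence were the genome-matched share, both kinds of phased loci, the 24-nt share upstream of genes and the genome-matched alternatives. No paired analysis was possible because 1 library was analysed. Depth limits the families under 3 reads (0.641 RPM) and the number of distinct sequences.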

Other observations

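All counts in this part were chosen after seeing the data. Of the 2416 exact 21-nt pairs, 2 held a sequence of a listed family, but miRNA duplexes usually hold mismatches and would be missed by this criterion. Among all the exact 21-nt pairs was GACGGAGCTGTGGCAGACTGC with 1170 reads and its partner AGTCTGCCACAGCTCCGTCGA with 55 reads.

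The paired 21-nt sequences differed in their 5' base from the rest. The more abundant strand of a pair began with C in 43.8% of cases (41.4 to 46.3, 1600 sequences) and the less abundant strand in 45.8% (1666 sequences). Of the 4330 paired 21-nt sequences, only these were compared by strand. The share was 24.1% among unpaired 21-nt sequences, 25.8% among unpaired ones with at least 2 reads, and 26.9% among those paired at the 4 neighbouring overlaps. The unpaired set held 136616 of the 143757 distinct 21-nt sequences, so some without a 19-nt partner are not in it. U was less frequent in the pairs, at 14.6% of the more abundant strands and 9.90% of the less abundant ones, against 34.3% of unpaired 21-nt sequences. It was 40.0% among the more abundant strands paired at the 4 neighbouring overlaps. The excess of C was not limited to 21 nt. Of the 34275 paired 24-nt sequences, 9913 more abundant strands and 10255 less abundant ones were compared. The more abundant strands began with C in 28.5% of cases and the less abundant ones in 35.4%. The share of C was 17.4% among unpaired 24-nt sequences and 20.96% among those paired at the 4 neighbouring overlaps. A was less frequent in the 24-nt pairs, at 26.9% of the more abundant strands and 19.1% of the less abundant ones. It was 43.9% among unpaired 24-nt sequences and 40.5% among the more abundant strands paired at the 4 neighbouring overlaps. Where the pairs lie in the genome, and what gives rise to them, was not analysed here.

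Substitutions in miR168 reads, which include read errors, were counted at its main sequence. It had 445718 reads, and 28084 more reads differed from it by 1 substitution, with 63 of the 63 possible variants seen. This is 0.300% per base. The most frequent was G17T, counted from 1 at the 5' end of the miRNA, at 0.707% of the unchanged reads, and G-to-T changes made up 31.8% of all. The most abundant 24-nt sequence outside the listed families and structural references was ACCTGCTCTGATACCATGTTGTGA with 6715 reads.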
